A study of Glycine max
Meloidogyne hapla and Medicago truncatula
Meloidogyne hapla with 23 samples.

How the data were processed

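Total RNA from nematode galls of Medicago truncatula and soybean roots was extracted with RNeasy columns and made into TruSeq libraries, per the labels' protocols. Plants were 4 weeks old when each pot received 2500 freshly hatched juveniles of Meloidogyne hapla, and galls were cut out 3 weeks later. The 23 libraries were grouped by host and strain as the labels name them, and the labels call them biological replicates. Soybean VW9 replicate 7 has no library, because its RNA yield was too low per the labels.

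The authors deposited a table of raw counts per plant gene for each host and a table of normalized values. HISAT2, HTSeq 2.0.2 and edgeR are named in the submitters' processing notes, and the genome builds, annotations and strand settings are not given in the sources used here. Whether reads shared between near-identical gene copies were divided among them or left out was not examined, which applies to the NIN, leghemoglobin and Rhg1 copies. The deposited normalized values are a signal adjusted to a common library size. For genes with over 500 counts in every library (9372 in Medicago and 6757 in soybean) the ratio to the raw count was nearly constant within a library, with every gene within 0.0629% of the library's median ratio in Medicago and 0.119% in soybean, and it varied at low values. They were used in an alternative test only. The count tables hold 50894 Medicago and 52872 soybean genes, of which 14773 and 5273 had 0 counts in every library. Units and tests matched those assumed in the design.

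Per-library totals of 34505404 to 47233135 counts in Medicago and 16947349 to 42715931 in soybean set the precision. Within each host, genes were kept by edgeR's filterByExpr, leaving 24242 and 36825, scaled by TMM and fitted with the robust quasi-likelihood model (glmQLFit and glmQLFTest), with strain as the only term. Benjamini-Hochberg adjustment was made over the genes tested, with a threshold of 0.05. Standard errors were taken as the absolute log2 fold change divided by the square root of F. The biological coefficient of variation was 0.417 in Medicago and 0.397 in soybean. CPM values are TMM-scaled for tested genes and per total count for the others. Principal components used log2 CPM with a prior count of 2. Group differences in library totals, detected genes and first-component scores were tested by exact two-sided permutation as 1 family of 6 tests. Library totals gave p = 0.714 in Medicago and p = 0.130 in soybean, and detected genes p = 0.943 and p = 0.502, all by the exact permutation test. Intervals of pooled ratios are exact binomial at 95%, and a gene at 0 counts was given a floor of 3 counts over the group.

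The tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0, with Python 3.11.15, scipy 1.17.1 and matplotlib 3.10.9. On simulated counts for 24242 Medicago genes, 3% of 100 genes changed 1 log2 unit and 66% of 100 changed by 2 were recovered, and 1.43% of the calls were false. For 36825 soybean genes, 53% and 87% were recovered and 5.41% of the calls were false. Each gene was simulated independently, and no change was placed in genes of low mean CPM. These shares therefore take no account of structure among the libraries other than strain. No pair of libraries agreed within sampling noise: the mean chi-square per gene was 33.7 to 616 in Medicago and 31.3 to 318 in soybean.

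The tests, gene list, alternatives and rule for named genes were fixed before the data were examined. Because the tables pair identifiers with no names, the rule allowed at most 2 genes per direction and host, those with the smallest p, plus every tested member of the list. All 5 Medicago genes that passed are named, the additional ones after their values were seen, as is Glyma.13G024100. The names of the list members, and what they are known to do, were written from memory of published annotation when the list was fixed. The tables do not pair them with the identifiers, so the names are unverified, in particular for the NIN and leghemoglobin copies of soybean. A reference table of soybean names matched 0 of the 52872 identifiers. Lists defined by gene descriptions could not be filled for this reason, so that only the list by identifier was tested. It was tested with camera (correlation preset to 0.01, or estimated) and fry.

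Nematode transcripts, the nematode share of counts, the strain by host interaction of nematode genes, scaling over both organisms and the nematode share as a covariate were part of the design and are not analysed here, since the tables used here hold plant genes. Plant genes were not matched between hosts, and a correlation over gene lists was not made with 1 list. Alternatives included RLE factors, filters on low counts (none, or at least 10 counts in every library of a strain), DESeq2, limma-voom, a test against a log2 fold change of 1, a non-robust fit, the replicate number as a block and each library left out. Others were added after the data were seen: 2 surrogate variables, limma on log2 of the deposited normalized value plus 1, and fits without the genes at least 5 times higher in every LM library, without Glyma.13G024100, without LM replicate 1 and VW9 replicate 1 in Medicago, and of the lists without their largest change.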

Results

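Root galls formed by the northern root-knot nematode Meloidogyne hapla, a parasite that feeds from enlarged cells in the root, were profiled by RNA sequencing in 2 legume hosts. The plants were Medicago truncatula Jemalong A17, a model legume, and soybean (Glycine max) Williams 82. Each plant received 1 of 2 nematode strains, LM or VW9, and galls were collected 3 weeks after inoculation. The 23 libraries fell into 4 groups, with 4 LM and 4 VW9 libraries from Medicago and 8 LM and 7 VW9 libraries from soybean. Counts assigned to Medicago genes ranged from 38604871 to 43052359 per library in LM galls and from 34505404 to 47233135 in VW9 galls. In soybean the totals ran from 24297041 to 42715931 in LM galls and from 16947349 to 40009464 in VW9 galls. All fold changes are given as VW9 minus LM, so that a negative value marks a gene that was lower in VW9 galls.

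The Medicago comparison asked which plant genes differed between galls of the 2 strains. A total of 5 genes fell in VW9 galls relative to LM galls and 0 rose, among 24242 genes tested with edgeR. These 5 genes had at least 165 counts in every LM library, and far lower levels, of at most 1.40 CPM, in every VW9 library. Galls can also hold nematode RNA, and whether these reads came from the plant or the nematode was not tested. Medtr7g016600 had a library-scaled count (CPM) of 21.05 ± 7.58 in LM galls and 0.127 ± 0.0748 CPM in VW9 galls (SD, n = 4 each). Medtr6g015975 had 23.1 ± 6.31 CPM in LM galls against 0.609 ± 0.248 CPM in VW9 galls (SD, n = 4 each). Medtr8g087860 was represented by 963 counts over the LM libraries and by 0 counts over the VW9 libraries, and was thus at least 312-fold higher in LM galls when 3 counts over the VW9 group are taken as the floor.

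The fitted log2 fold change was -7.30 for Medtr7g016600 (SE 0.455, edgeR adjusted p = 0.00321) and -5.24 for Medtr6g015975 (SE 0.348, edgeR adjusted p = 0.00321). Medtr3g084980 reached -8.10 (SE 0.592, edgeR adjusted p = 0.00461), with 1687 counts in LM galls and 5 in VW9 galls. Medtr3g005530 reached -4.78 (SE 0.465, edgeR adjusted p = 0.0257), with 3953 counts in LM galls and 124 in VW9 galls. Medtr8g087860 had an edgeR adjusted p of 0.0139. Pooled over libraries, LM galls held 172 times the Medtr7g016600 signal of VW9 galls (95% exact binomial interval 113 to 279), 41.5 times that of Medtr6g015975 (33.9 to 51.4), 328 times that of Medtr3g084980 (140.2 to 1011) and 30.98 times that of Medtr3g005530 (25.9 to 37.4). These intervals cover counting error only. For all 5 genes every LM library lay above every VW9 library. Over all tested genes 1532 separated the strains in this way, against 692.6 by chance (2.86% of the genes).

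Genes at p below 0.05 before adjustment numbered 2228 (916 higher and 1312 lower in VW9 galls), against 1212.1 by chance. This number depended on single libraries, with 1306 of 24623 genes without LM replicate 3, 1412 without LM replicate 4, 3020 without VW9 replicate 1 and 4568 without LM replicate 1 and VW9 replicate 1 together. DESeq2 called 604 genes, 212 higher and 392 lower, and limma-voom called 7, all of them lower. With any single LM library left out, 3 genes passed, and Medtr7g016600, Medtr6g015975 and Medtr3g084980 passed in each of those fits. Medtr3g005530 also failed to pass without VW9 replicate 2, 3 or 4, and Medtr8g087860 with 2 surrogate variables (log2 fold change -11.02, edgeR adjusted p = 0.120). On the first principal component, which held 43.1% of the variance, the library of LM replicate 1 (score 55.1) lay among VW9 replicates 2, 3 and 4 (24.4 to 122), and VW9 replicate 1 (-79.0) lay beside the other LM libraries (-59.6 to -35.9). The difference of the group means on this component was not significant (exact two-sided permutation p = 0.371, adjusted p = 0.743 over 6 such tests).

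**Figure D1:**
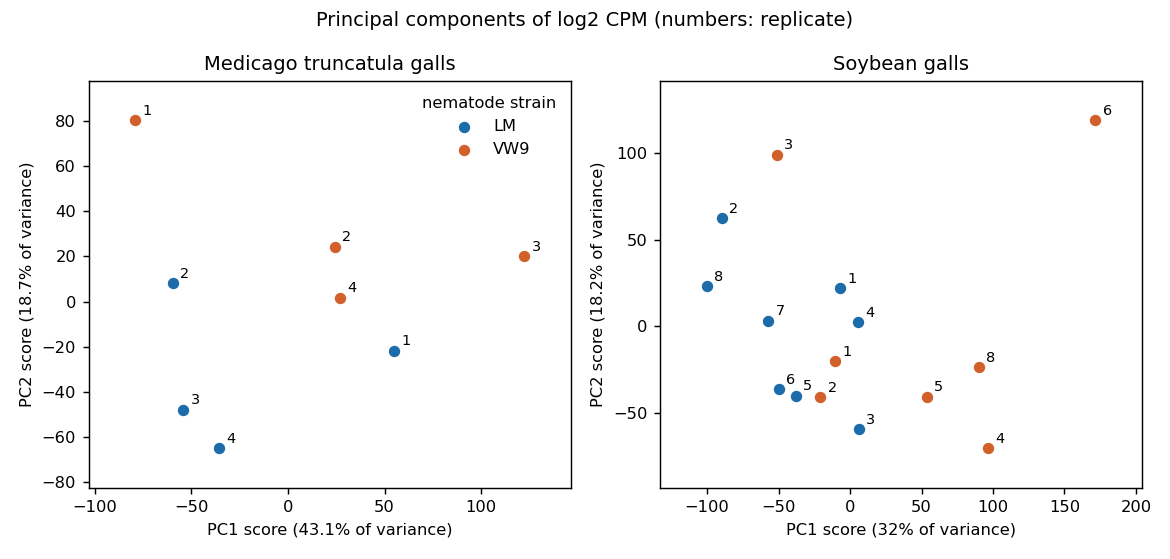
Scores of each library on the first and second principal components of log2 CPM, for Medicago galls (left, 4 LM and 4 VW9 libraries) and soybean galls (right, 8 LM and 7 VW9 libraries). Numbers are replicates, and the axes give the share of variance of each component. Medicago LM replicate 1 sits at 55.1 on the first component and VW9 replicate 1 at -79.0, each on the side where most libraries of the other strain lie.

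None of the 17 tested Medicago genes on a list for rhizobial or mycorrhizal signalling passed the edgeR test over all genes. DESeq2 passed 1 of them, LYK3 (adjusted p = 0.0107, and 0.0107 to 1 over all settings tried). The list, fixed before the data were examined and with names not checked against an annotation, had 20 members, of which 17 were tested, 5 with positive and 12 with negative fold changes. Adjusted over the list alone, 1 member passed in edgeR: LYK3, which encodes a LysM receptor kinase required for rhizobial entry. LYK3 fell by 1.498 on the log2 scale (SE 0.356, edgeR adjusted p = 0.0471 over the list alone and 0.300 over all genes), from 9.55 ± 3.94 CPM in LM galls to 3.38 ± 0.692 CPM in VW9 galls (SD, n = 4 each). NFP, the partner Nod factor receptor, had a log2 fold change of -1.56 (SE 0.589), and the transcription factor ERN1 one of -1.58 (SE 0.84). The transcription factor genes NIN and NF-YA1, which drive nodule formation, stood at +1.48 (SE 0.619) and +2.30 (SE 0.774). DMI2, NSP1 and NSP2, of the shared symbiosis pathway, stood at -0.08 (SE 0.294), -0.10 (SE 0.293) and +0.12 (SE 0.756). SUNN, a receptor kinase that limits nodule number, had +0.58 (SE 0.299), and the cytokinin receptor CRE1 had -0.40 (SE 0.413). Before adjustment the edgeR p was 0.00277 for LYK3, 0.0171 for NF-YA1, 0.0282 for NFP and 0.0429 for NIN. The remaining tested members lay between -0.78 for IPD3 and +0.75 for RPG.

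The median log2 fold change of the tested list was -0.37 and the mean -0.16, and no difference of the list from other genes was detected (camera p = 0.323, and p = 0.651 with an estimated correlation). fry gave p = 0.512 for a shift in one direction and p = 0.126 for changes in either direction. CLE12, CLE13 and ENOD11 were too low to test, with at most 13 counts in any library. The LYK3 call was lost when RLE factors replaced TMM, in limma-voom, in the test against a log2 fold change of 1, with 2 surrogate variables, with the deposited normalized values, without LM replicate 1 and VW9 replicate 1 together, and on leaving out any single library other than LM replicate 2. In DESeq2 LYK3, NF-YA1 and NFP passed over the list alone. LM replicate 1, which lay with VW9 libraries on the first component, was the highest LM library for NF-YA1 at 1.75 CPM, against 0.509 to 0.593 CPM in the others.

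**Figure D2:**
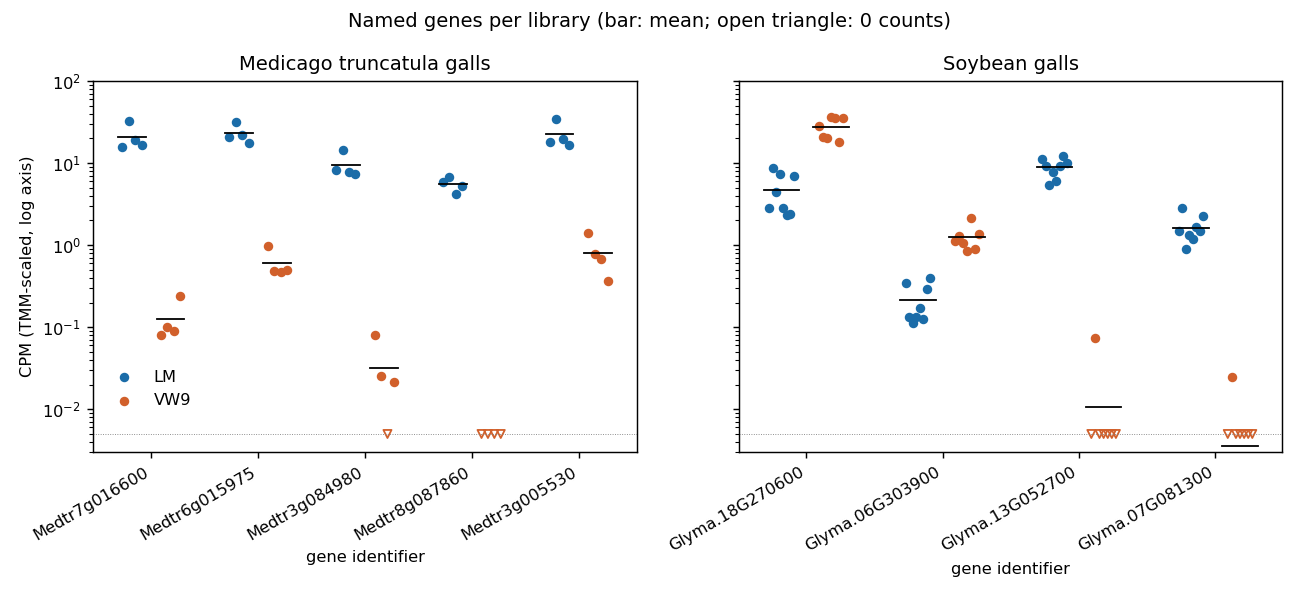
CPM per library on a log axis for the 5 Medicago genes (left) and 4 soybean genes (right) named from the comparison of strains, with LM libraries in blue and VW9 libraries in orange. Bars are group means and open triangles mark libraries with 0 counts. Every LM library of Medtr7g016600 lies between 15.9 and 32.2 CPM and every VW9 library between 0.0794 and 0.238 CPM.

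In soybean galls the same question returned 217 genes in edgeR, of which 76 rose and 141 fell in VW9 galls. The genes with the smallest p among those that fell, Glyma.13G052700 and Glyma.07G081300, were present in LM galls and close to absent in VW9 galls. Whether their reads came from the plant or the nematode was likewise not tested. Glyma.13G052700 had 8.92 ± 2.36 CPM in LM galls (SD, n = 8) and 0.0106 ± 0.028 CPM in VW9 galls (SD, n = 7), from 2230 and 3 counts. Among the genes that rose, Glyma.18G270600 went from 4.74 ± 2.57 CPM in LM galls (SD, n = 8) to 27.8 ± 8.14 CPM in VW9 galls (SD, n = 7). Glyma.06G303900 went from 0.214 ± 0.116 CPM (SD, n = 8) to 1.25 ± 0.424 CPM (SD, n = 7).

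The fitted log2 fold change was -8.86 for Glyma.13G052700 (SE 0.507, edgeR adjusted p = 3.96e-07) and -7.48 for Glyma.07G081300 (SE 0.528, edgeR adjusted p = 3.88e-06). Pooled over libraries, LM galls held 533 times the Glyma.13G052700 signal of VW9 galls (95% exact binomial interval 182 to 2588) and 287 times that of Glyma.07G081300 (51.2 to 11360), the latter from 400 counts against 1, and here too the intervals cover counting error only. All VW9 counts of both genes came from VW9 replicate 2, and without that library the fitted log2 fold changes were -11.01 and -8.57. Glyma.18G270600 rose by 2.56 on the log2 scale (SE 0.321, edgeR adjusted p = 0.00235) and Glyma.06G303900 by 2.50 (SE 0.338, edgeR adjusted p = 0.00427). In each of these 4 genes all libraries of one strain lay above all libraries of the other. Over all tested genes 196 separated the strains in this way, against 11.45 by chance (0.0311% of the genes). The called changes ran from -8.86 to +2.56, and 15 genes fell by at least 3 on the log2 scale while 0 rose by as much. A change of at least 1 in size was fitted for 37 of the genes that rose and 74 of those that fell.

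Before adjustment 6811 of the 36825 tested soybean genes had p below 0.05 (3372 higher and 3439 lower), against 1841.2 by chance, and DESeq2 called 2048 (721 higher and 1327 lower). The number of calls depended on single libraries, from 57 without VW9 replicate 8 to 682 without VW9 replicate 3, while a test against a log2 fold change of 1 left 16, without Glyma.06G303900 (edgeR adjusted p = 0.0743). On the first principal component VW9 libraries had a mean score of 47.1 ± 79.0 (SD, n = 7) and LM libraries -41.2 ± 41.1 (SD, n = 8; exact two-sided permutation p = 0.0168, adjusted p = 0.101 over 6 such tests). VW9 replicate 6, the shallowest library, had the highest score (171.7), and VW9 replicate 3 (-51.2) lay below the other VW9 libraries (-20.8 to 171.7) and within the range of LM libraries (-100.4 to 6.29).

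**Figure D3:**
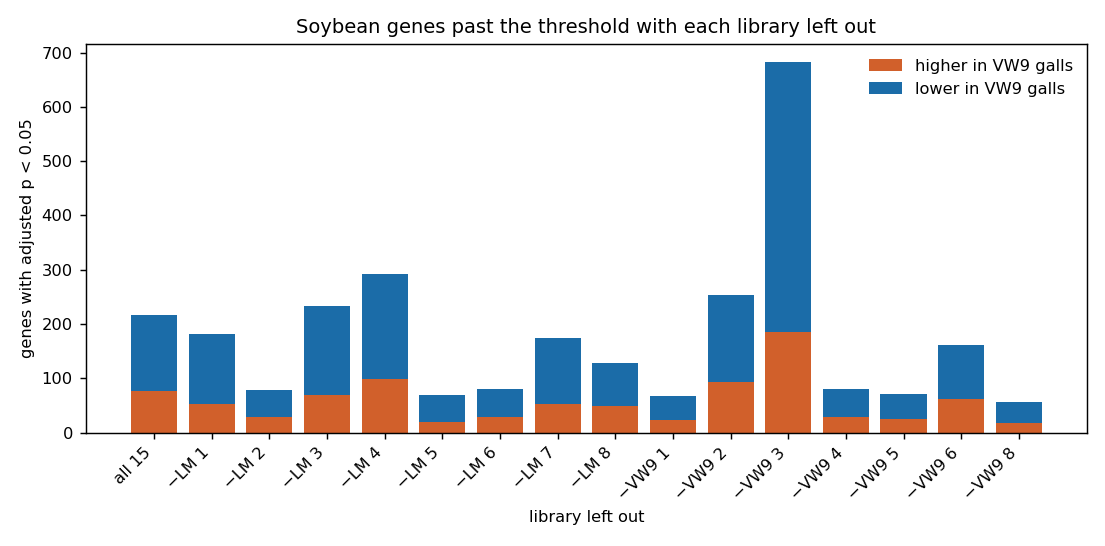
Number of soybean genes with an edgeR adjusted p below 0.05 in all 15 libraries (217) and with each library left out in turn, divided into genes higher (orange) and lower (blue) in VW9 galls. The count ranged from 57 without VW9 replicate 8 to 682 without VW9 replicate 3.

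In both hosts a small set of genes was far higher in every LM gall library than in any VW9 library, by a measure set after these values were seen. It required the lowest LM library to be at least 5 times the highest VW9 library, with at least 5 counts in every LM library. It held for 8 Medicago genes, among them all 5 that passed the test, and for 9 soybean genes, all of which passed. The reads of these genes were not traced to plant or nematode. The reverse pattern was met by 0 genes in each host. Without Medicago LM replicate 1 and VW9 replicate 1, 17 genes met the measure for LM and 13 for VW9 in the other 6 libraries. The measure is easier to meet with fewer libraries and no other pair was left out. Whether the contrast in Medicago rested on these 2 libraries was therefore not tested. The 8 Medicago genes together made up 84.0 ± 26.7 CPM in LM galls and 1.67 ± 0.681 CPM in VW9 galls (SD, n = 4 each). The 9 soybean genes together made up 30.03 ± 8.75 CPM in LM galls (SD, n = 8) and 0.124 ± 0.120 CPM in VW9 galls (SD, n = 7). Apart from these, 208 soybean genes and 0 Medicago genes passed in edgeR, and 132 of the 208 were lower in VW9 galls. The totals of the hosts cannot be compared as sizes of response. Soybean had 8 LM and 7 VW9 libraries, against 4 of each in Medicago. Simulated changes of 1 log2 unit were recovered for 53% of the changed genes in soybean and 3% in Medicago. Whether the response differed between hosts was not tested, since genes of the 2 plants were not matched here.

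Of the soybean genes listed for cyst nematode resistance, under names likewise not checked, 2 members of the Rhg1 locus were lower in VW9 galls, adjusted over the list alone. Glyma.18G022700, a wound-inducible gene of that locus, fell by 1.08 on the log2 scale (SE 0.337, edgeR adjusted p = 0.0335 over the list alone and 0.129 over all genes), from 68.0 ± 36.3 CPM (SD, n = 8) to 32.1 ± 13.4 CPM (SD, n = 7). Glyma.18G022400, an amino acid transporter gene, fell by 0.49 (SE 0.181, edgeR adjusted p = 0.0462 over the list alone and 0.177 over all genes), from 55.0 ± 10.1 CPM to 39.1 ± 10.9 CPM. Glyma.18G022500, the α-SNAP gene of the locus, had a log2 fold change of +0.08 (SE 0.121). Rhg4, a serine hydroxymethyltransferase gene at another resistance locus, had -0.16 (SE 0.175). Of the NIN genes, NIN1a stood at -1.65 (SE 0.731) and NIN2b at +0.86 (SE 0.545). In libraries of either strain leghemoglobin transcripts, which mark rhizobial nodules, were nearly undetected: the 4 genes had 19 counts among 446834736 over all soybean libraries (0.0425 CPM), 11 of them in VW9 replicate 4. For the 2 leghemoglobin genes at 0 counts this depth allows up to 0.00671 CPM, apart from reads shared between copies, which may have been left out of the counts.

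Of the 12 soybean list members 6 were tested, 2 with positive and 4 with negative values, and 0 passed in edgeR over all genes, whereas DESeq2 passed 1, Glyma.18G022700 (adjusted p = 0.0344, and 0.0344 to 1 over all settings tried). Before adjustment the edgeR p was 0.00559 for Glyma.18G022700, 0.0154 for Glyma.18G022400 and 0.0392 for NIN1a. The median log2 fold change was -0.33 and the mean -0.41 (camera p = 0.103, and p = 0.243 with an estimated correlation, fry p = 0.095, and 0.229 for either direction). Both Rhg1 calls were lost on leaving out LM replicate 6, 7 or 8 or VW9 replicate 4 or 8, with 2 surrogate variables and in the test against a log2 fold change of 1. In DESeq2, and without VW9 replicate 1, NIN1a passed over the list as well. Without LM replicate 2 or 4 or VW9 replicate 3, Glyma.18G022700 alone passed over the list.

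**Figure D4:**
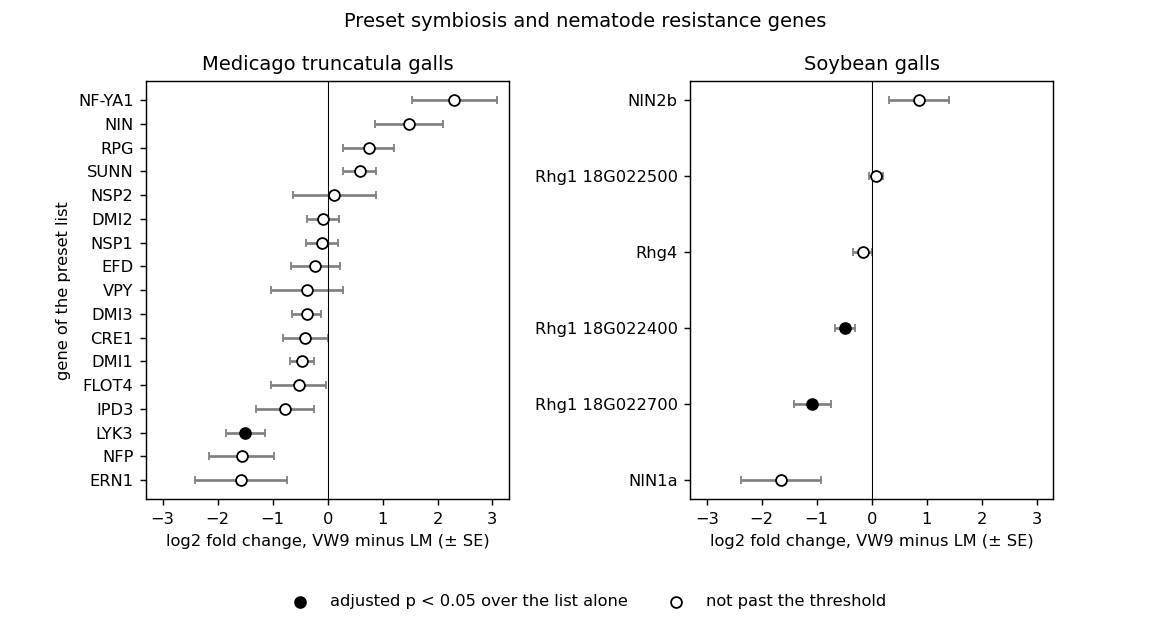
Fitted log2 fold change (VW9 minus LM, bars ± SE) of the 17 tested Medicago genes (left) and 6 tested soybean genes (right) of the list fixed in advance. Filled points passed adjusted over the list alone: LYK3 at -1.498 in Medicago, and Rhg1 members Glyma.18G022700 at -1.08 and Glyma.18G022400 at -0.49 in soybean.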

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

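Of the tests below, those of library depth for the genes far higher in LM galls, of the correlation of these genes with an LM library left out, of a wrong label on soybean VW9 replicate 3 and of an exchange of 2 Medicago libraries were chosen only after the values they rest on had been seen. A library was singled out where its distance to the nearest other library, as a share of the range of its group, exceeded Dixon's limit. This held for 12 of 80 groups of values, and chance gives it to about 1 in 20.

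In Medicago, the total of LM replicate 3 was low at 38604871 counts against at least 42504182 in the others (ratio 0.877). The most abundant gene took 1.45% of the counts of VW9 replicate 1, against at most 0.819% in the other VW9 libraries (0.835). NF-YA1 (Medtr1g056530) was high in LM replicate 1 at 1.75 CPM (0.932). Medtr3g084980 was high in LM replicate 2 at 14.5 CPM (0.867). Medtr6g015975 was high in VW9 replicate 1 at 0.980 CPM (0.952), and Medtr7g016600 in VW9 replicate 4 at 0.238 CPM (0.862), both far below every LM library.

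In soybean, LM replicate 1 had few detected genes (39819, ratio 0.596), as did VW9 replicate 6 (38570, ratio 0.573). In VW9 replicate 6 the most abundant gene, Glyma.13G024100, took 6.64% of the counts, against at most 0.809% for the top gene of the other VW9 libraries (0.929). Glyma.06G303900 was high in VW9 replicate 5 at 2.11 CPM (0.604). The 3 counts of Glyma.13G052700 and the single count of Glyma.07G081300 in VW9 galls all came from VW9 replicate 2 (ratio 1.0 each).

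The genes at least 5 times higher in every LM library than in any VW9 library numbered 8 in Medicago and 9 in soybean. After all libraries were thinned to the smallest total, 8 of 8 and 8 of 9 kept the 5-fold gap. Medtr8g087860, Glyma.03G019400, Glyma.08G250700 and Glyma.14G027251 had 0 counts in every VW9 library. They could not lose the gap, so for them the thinning decides nothing. The other genes that kept it did so at equal depth. They had been chosen by a gap in CPM, which is already scaled for depth. Many gaps were also far wider than 5-fold, as for Medtr7g016600 (at least 15.9 CPM in LM and at most 0.238 CPM in VW9 libraries). Their outcome was thus largely fixed in advance, and the thinning says little about depth. Other splits of the libraries separated up to 11 genes in Medicago and 8 in soybean, and since the measure was set on the labelled split, chance is not excluded for these sets. Within LM libraries the soybean genes moved together, with a median pairwise correlation of 0.623 (percentile 100 of matched random sets, whose median was -0.00834), as reads from 1 source such as the nematode or another organism could produce, whereas the 0.568 of Medicago (percentile 98.6, median -0.0137) rested on LM replicate 2, without which it was -0.214 (percentile 37.4), and decides nothing. Plant genes induced together by LM could move in the same way, and this biological explanation stays open and untested, because neither sequences nor nematode counts were used.

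In Medicago 2 of 35 splits gave at least 5 calls, so that chance is not excluded for the count of 5, and the other, LM replicate 1 with VW9 replicates 2, 3 and 4 against the rest, gave 715, which points to a structure of the samples other than the labelled strain. After thinning to the smallest library 96.5% of those calls were kept, which argues against depth, and no biological explanation was tested. Whether LM replicate 1 and VW9 replicate 1 were exchanged cannot be told apart from another structure. In the other 6 libraries 30 genes separated the strains 5-fold. In 46.7% of these genes the 2 libraries differed from each other at least 5-fold against their labels, and in 30% at least 5-fold with them. This count did not compare either library with the level of a strain. Of the 17 marking LM, 9 followed the labels and 3 the exchange, while of the 13 marking VW9, 0 followed the labels and 11 the exchange, and with LM-marking genes chosen by leaving out 1 library at a time LM replicate 1 stood at 77.8% and VW9 replicate 1 at 3.18% of the LM mean, although that choice takes the label of the other library as given. An earlier version of the test took only the summed level of the 17 genes, 60% of the LM mean in LM replicate 1 and 14.8% in VW9 replicate 1, and its bounds were changed after these values were seen, so it was set aside for the count over both kinds of gene.

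The 217 soybean calls became 682 without VW9 replicate 3. A wrong strain label on that library is argued against by the genes that mark LM galls, chosen from the other libraries, which stood at 0.163% of the LM mean. Its score on the first principal component, -51.2, nevertheless lay within the range of LM libraries. Of 676 genes called without it, 62.4% lay nearer the LM mean than the mean of the other VW9 libraries. Because leaving this library out raised the calls, such a share is partly built in and decides nothing about the label. Of 100 splits of the 15 libraries 1, the real one, gave as many calls as 217, and at most 19 were found in another. This argues against chance, but the other splits were a random draw from all possible ones, so chance is not excluded. Why VW9 replicate 3 lay apart was not found, and no biological explanation was tested.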

How the results depend on the processing

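Surrogate variables, the deposited normalized values and fits without genes or with 2 libraries removed were tried only after the data had been seen. The 5 Medicago calls numbered 5 to 7 under the other scaling, filter, limma and fold settings. They became 0 without the genes at least 5 times higher in every LM library, 604 with DESeq2, 3 without LM replicate 1 and VW9 replicate 1 together, and 3 to 6 on leaving out single libraries (3 without each LM replicate). With 2 surrogate variables 6 passed, 1 of them higher and 4 shared with the 5. The soybean count was 169 to 306 under most settings (306 with 2 surrogate variables, 138 of them among the 217), 16 in the test against a log2 fold change of 1, 2048 with DESeq2, and 57 to 682 without single libraries: 78, 70, 81 and 128 without LM replicates 2, 5, 6 and 8, and 68, 682, 81, 71 and 57 without VW9 replicates 1, 3, 4, 5 and 8. The cause was not tested. The list tests changed no call, with camera p of 0.0664 to 0.831 in Medicago and 0.0549 to 0.206 in soybean over single libraries left out. Few counts limit the genes near absence, whose fitted changes depend on the prior count.

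Replicate numbers did not pair the libraries: same-numbered libraries correlated at -0.60 to 0.0136 in Medicago and -0.396 to 0.0581 in soybean, and none correlated best with its own number. With a replicate block, 0 Medicago and 6 soybean genes passed, not among them Glyma.18G270600 and Glyma.06G303900, whose log2 fold changes were 2.56 and 2.66 with the block (-7.34 for Medtr7g016600), and camera p was 0.438 and 0.0629 for the lists. Over the lists alone LYK3 and both Rhg1 genes no longer passed, and NIN1a did.

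Among named genes, 396 values in Medicago and 261 in soybean kept direction and side of the threshold, 19 and 3 lost the threshold and 1 each passed it with DESeq2 (LYK3 and Glyma.18G022700). Only genes past the threshold in the main fit could lose it, and most kept values were list members that stayed short of it. In Medicago all 19 lost values fell on the 5 called genes, most of them on Medtr3g005530 and Medtr8g087860. Signs reversed only in list members that had not passed over all genes. With 2 surrogate variables the log2 fold change was 0.31 for DMI2, -0.51 for NSP2, 0.13 for ERN1, 0.016 for EFD, 0.052 for CRE1 and 0.46 for FLOT4. NSP2 was also at -0.045 with the replicate block, -0.12 in limma-voom and -0.12 from the deposited values. Leaving out single libraries moved DMI2 from -0.25 to 0.12 (positive without LM 3, LM 4 or VW9 3), NSP1 from -0.37 to 0.094 (positive without LM 3, VW9 2 or VW9 4), NSP2 from -0.68 to 0.56 (negative without LM 2 or VW9 3), EFD from -0.50 to 0.24 (positive without LM 2), VPY from -0.65 to 0.049 (positive without LM 4) and, in soybean, Glyma.18G022500 from -0.013 to 0.14 (negative without VW9 3).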

Other observations

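The test of neighbouring genes below was chosen after the calls had been seen. In the order of their identifiers, 20 of the 217 soybean genes that passed had another gene of the same direction within 5 tested genes. Among 10000 random placements of as many calls the median was 6 and the 95th percentile 13 (permutation p = 0.0022). A hypothesis is that called genes lie in neighbouring positions. The count of 20 restates that pattern and is not separate support for it. Positions were taken from the order of identifiers, and shared reads between copies could have the same effect.

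Glyma.13G024100, singled out after its values were seen, was among the most abundant soybean transcripts in both strains and reached 63460 CPM in VW9 replicate 6, against 2228 to 8352 CPM in the other VW9 libraries. Its difference between strains did not pass (log2 fold change 1.80, SE 0.670, edgeR adjusted p = 0.183), and without VW9 replicate 6 the log2 fold change was 0.22 (SE 0.295, edgeR adjusted p = 0.760), from 3666 ± 1120 CPM in LM galls (SD, n = 8) and 4281 ± 2210 CPM in the other VW9 libraries (SD, n = 6). Without it before normalization 213 soybean genes passed, 208 of them among the 217.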
